A study of Rattus norvegicus with 8 samples.

How the data were processed

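MicroRNAs were measured on Agilent SurePrint G3 rat arrays, version 16.0, in retinal ganglion cells freshly purified from Sprague Dawley rats at E21 (3 arrays), P6 (3 arrays) and P30 (2 arrays). Per the labels, retinas were dissociated enzymatically, the cells were taken out magnetically with a ganglion cell isolation kit, and a single dye was put on 100 ng of RNA from each. Each array belonged to a separate biological replicate.

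The deposited intensity values, 1 file per array, were total signals per miRNA on a linear scale, made by the authors with Agilent Feature Extraction 9.5.3.1 (background subtraction, probes and replicate spots combined) and without scaling between arrays. Each file held 699 features, of which 677 were miRNAs and 22 were controls, and undetected features shared the value 0.1. The deposited log2 values in the series table were made by the authors with GeneSpring GX 11.5 and a 75th percentile shift. Each of their columns equalled log2 of that array's own signals minus a single constant, to within 1.19e-06 log2 units on each array. Which features the authors took the percentile over is not stated. The column medians of that table were -10.33, -12.19 and -11.81 for E21, -10.50, -11.68 and -12.09 for P6, and -10.74 and -10.89 for P30.

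From the intensities, each array was divided by its 75th percentile over the 163 miRNAs detected on all 8 arrays and multiplied by the mean of these percentiles, values under 1 were set to 1, and log2 was taken. As the files carry no detection flag, detected meant above the shared lowest value. A miRNA was tested when it was detected on every array of at least 1 stage, which left 254. One mean per stage was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with 5 residual and 1.24 prior degrees of freedom. The 3 stages were compared in pairs with the two-sided moderated test of limma, and over all stages with its moderated F test. p-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 was called. An exact permutation test of 3 against 3 arrays (two-sided), or of 3 against 2, could not go below 0.1 for a single miRNA. An adjusted p depends on the spread that limma pools over miRNAs.

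For a miRNA undetected on an array, the log2 difference of the fit and its p depend on the value of 1 set for it. A stage undetected on all its arrays adds no spread, so such a p can be too small. Beside the fitted difference, a difference was computed with each undetected value raised to the lowest detected signal of its array. This gives the "at least" folds and the medians at the bound. It was used in the permutation tests of precursor arms, neighbouring genes and the Dlk1-Dio3 spread, and was not tested otherwise. List tests used the fitted values, so their p-values do not belong to medians at the bound. A single miRNA's own detection limit may lie above the lowest detected signal of the array. Named miRNAs were chosen by a rule fixed before the data were examined. The rule took the 8 largest rises and the 8 largest falls per comparison among called miRNAs whose arrays did not overlap and which were detected on every array of the higher stage. It added every member of miR-17~92 and, from each list, up to 4 tested members with the smallest adjusted p. The largest rises and falls were picked on the differences with undetected values at the bound, so the order within them is not an order of true size. Where a list's account names further called members, these were taken from the same list.

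The 15 lists of miRNA families and clusters and the 11 lists of markers of other cell types were fixed before the data were examined, as were the tests and all alternatives except those on the low-signal arrays. The 17 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with camera at an estimated correlation and with fry. Over the 3 comparisons camera called 5, 6 and 5 lists with the preset correlation and 0 with an estimated one, where 3, 3 and 2 had an unadjusted p under 0.05, and fry called 8, 12 and 11. The estimated correlation was 0.101 for miR-17~92, -0.0297 for its paralogs and 0.772 for let-7. For the paralogs it lay below the preset, yet the unadjusted camera p at P6 versus E21 went from 0.000899 to 0.0187. With an estimated correlation, camera also takes its p from the 5 residual degrees of freedom instead of a far larger number. That alone raises the p, so the loss of calls is not due to correlation between members alone. A p that misses the threshold there does not show that correlated members account for a list's shift. Fry asks whether the members of a list move one way and does not compare them with other miRNAs.

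Replicate numbers were checked for pairing. Over the tested miRNAs, deviations from the stage mean correlated between E21 and P6 arrays of the same number at 0.634, 0.528 and 0.491. Different numbers were as close for E21 replicate 2 with P6 replicate 3 (0.504) and E21 replicate 3 with P6 replicate 2 (0.451), and P30 arrays gave -0.0985 to -0.0471 with E21 and P6 arrays of the same number. The labels state no pairing, so no block was used in the reported fit and replicate number was tried as an alternative. The within-stage correlation over miRNAs detected on all arrays was 0.996 for P6 replicates 2 and 3, 0.981 for E21 replicates 2 and 3 and 0.976 for P30, and 0.858 to 0.925 for pairs with replicate 1 of E21 or P6.

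The alternatives were other scalings between arrays (percentile over all miRNAs, quantile normalization, median centring, none, the authors' log2 values), a floor of 10, a started log with 16, no detection filter, only miRNAs detected on all 8 arrays, only the arrays of the 2 stages compared, eBayes with trend, array weights, a replicate block, a 2-fold minimum and leaving out each array in turn. Leaving out the low-signal arrays (replicate 1 of E21 and of P6), and fitting them as a batch block, were added after seeing the data. The procedure was tested on simulated data of 254 miRNAs with 60 changed. In the comparison of P6 with E21 it recovered 65.9% of 2-fold and 88.9% of 4-fold changes with 2.1 false calls on average, and in that of P30 with E21 62.3% and 87.1% with 1.72. In the comparison of P30 with P6, simulated without effects, it made 0.06 false calls. At an unadjusted p under 0.05, camera called 98% of simulated lists of 6 shifted by -2 and 0% of unshifted ones. The simulated errors were normal and independent between miRNAs, with spreads taken from miRNAs detected on all arrays. They held no undetected values and no shared deviation of replicate 1. These rates therefore cannot show how the preset correlation or undetected values act in the real data.

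Names of miRNAs were matched to genes of the GRCr8 annotation through synonyms, which gave 1 gene for 224 names. This served only to find neighbouring genes, and no coordinates are given because no genome came with the series. Control features and 369 miRNAs never detected were left out of all tests. Array signals give no molecule counts, so no counting intervals apply.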

Results

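MicroRNA levels were measured in retinal ganglion cells, the neurons whose axons form the optic nerve, freshly purified from Sprague Dawley rats at embryonic day 21 (E21), postnatal day 6 (P6) and postnatal day 30 (P30). Each biological replicate was hybridised to 1 one-colour array, which gave 3 arrays for E21, 3 for P6 and 2 for P30. The arrays carried 677 rat miRNAs, and between 202 and 282 of them were detected per array. The summed miRNA signal was 34756 in E21 replicate 1 and 40411 in P6 replicate 1, against 72656 to 122745 on the other 6 arrays. Levels are given as log2 of the signal after scaling between arrays, as mean ± SD over the arrays of a stage, and the small number of arrays limits their precision. A difference against a stage in which a miRNA was undetected on 1 or more arrays is given as "at least" a fold, with undetected values set at the lowest detected signal of that array. The detection limit of a single miRNA is not known and may lie above that signal. These folds therefore depend on that setting and are not strict lower bounds.

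**Figure D1:**
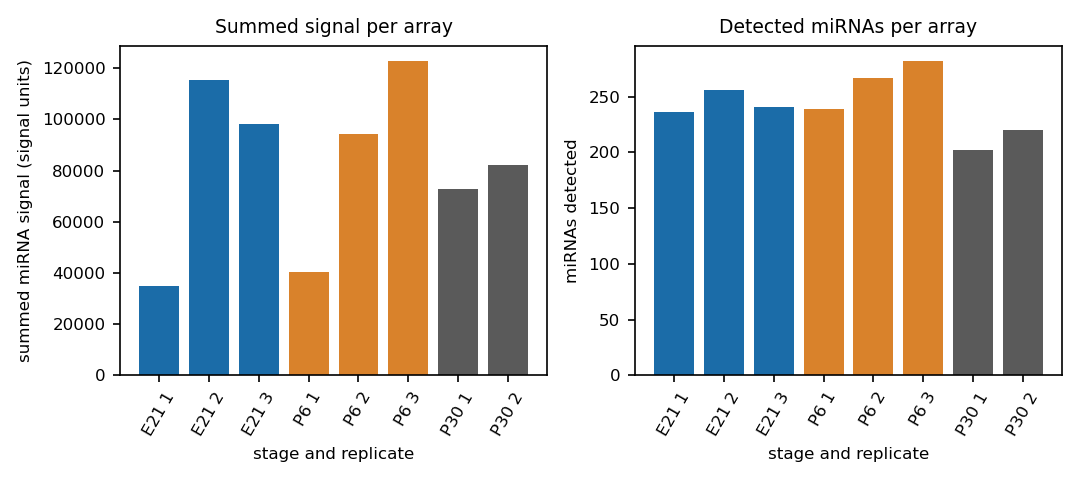
Summed miRNA signal in signal units (left) and number of detected miRNAs (right) for each array, 1 bar per array, coloured by stage. The summed signal was lowest on E21 replicate 1 (34756) and P6 replicate 1 (40411), and P30 replicate 1 had the fewest detected miRNAs (202).

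The series is named for miR-19a, the phosphatase gene Pten and the loss of axon regenerative capacity with age, so the first question was how miR-19a and the other miRNAs differed between the stages. From E21 to P6, miR-19a fell 3.07-fold, from 8.76 ± 0.30 (SD, n = 3) to 7.14 ± 0.19 (SD, n = 3), with a log2 difference of -1.62 (SE 0.196, adjusted p = 0.00178 in the limma fit). The other members of the miR-17~92 polycistron, a cluster expressed in embryonic and dividing cells, were lower too. miR-18a fell 4.39-fold, miR-92a 4.36-fold, miR-17-5p 3.70-fold and miR-19b 2.57-fold. miR-20a went from 10.87 ± 0.24 (SD, n = 3) to 8.91 ± 0.06 (SD, n = 3) and did not pass in the fit to all stages (adjusted p = 0.136). Its adjusted p was 0.00126 in the fit to the E21 and P6 arrays alone, and ranged from 0.000215 (floor of 10) to 0.460 over 14 alternatives. The fit to all stages also takes in the P30 spread of miR-20a, where 1 of 2 arrays was undetected and set to 1 signal unit (SD 2.37).

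As a group, 5 of the 6 miR-17~92 members were called lower at P6 (6 when adjusted over the list alone), with a median log2 difference of -1.92 and camera adjusted p = 0.00159. With an estimated correlation the adjusted p was 0.177. The study chose miR-19a on these samples, so neither this cluster nor its count is independent evidence of the direction. All 5 tested members of the paralogs of this cluster, around miR-106b and miR-106a, were lower, among them miR-20b-5p (3.89-fold) and miR-93 (2.94-fold), with a median of -1.56 and 5 adjusted over the list alone (camera adjusted p = 0.00764, and adjusted p = 0.177 with an estimated correlation). Of 15 tested miRNAs reported to target Pten, 7 were lower and 0 were higher (7 and 1 adjusted over the list alone), with a median of -1.38 (camera adjusted p = 0.0123). The adjusted p was 0.275 with an estimated correlation and 0.112 without both low-signal arrays, and 0.0847 without E21 replicate 1. Of these 7, miR-17-5p, miR-19a, miR-19b, miR-93 and miR-106b are also members of the clusters above, and the others were miR-216a and miR-217. The list is therefore not independent of those clusters or of the study's choice of miR-19a. Probes for miR-17-5p, miR-20a, miR-20b-5p, miR-93 and miR-106b, and those for miR-19a and miR-19b, can share signal, so single members of these families are uncertain.

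**Figure D2:**
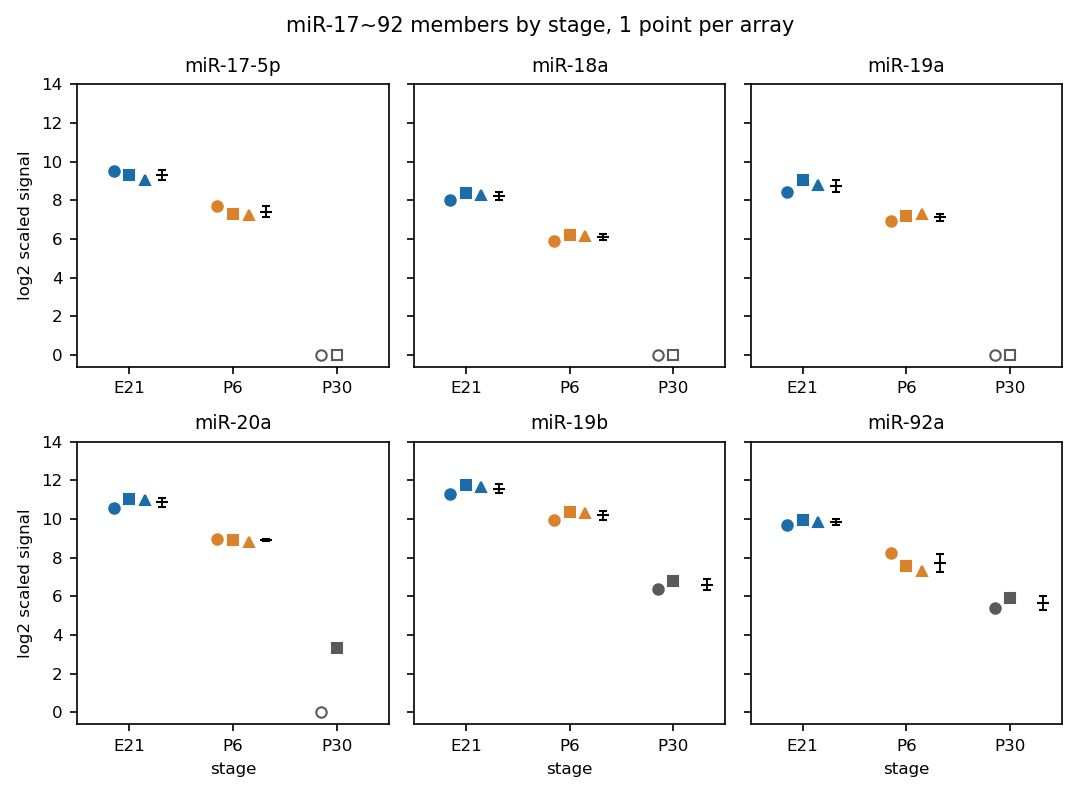
Log2 scaled signal (vertical axis) of the 6 miR-17~92 members at E21, P6 and P30 (horizontal axis), with 1 filled point per array, circles, squares and triangles for replicates 1, 2 and 3, open points at 0 for arrays where the miRNA was undetected, and a bar for the mean ± SD of stages in which all arrays detected it. All 6 miRNAs sat highest at E21, and miR-17-5p, miR-18a and miR-19a were undetected on both P30 arrays.

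The 8 largest falls from E21 to P6 were led by miR-216b-5p (5.97-fold), miR-217 (4.95-fold), miR-301b (4.93-fold) and miR-216a (4.52-fold), and also took in miR-18a, miR-92a, miR-20b-5p and miR-363, the last at least 4.21-fold with detection on 2 of 3 P6 arrays. Of the 5 tested members of the progenitor-associated list of miR-130, miR-301 and miR-335 members, miR-301b and miR-130a were lower (2 adjusted over the list alone). The list as a whole did not pass (median -0.94, camera adjusted p = 0.0642, and adjusted p = 0.625 with an estimated correlation). Its adjusted p was 0.0215 without P30 replicate 1 and 0.0267 without P30 replicate 2 (0.547 and 0.560 with an estimated correlation), and it passed in 7 of 17 alternatives, at 0.0361 in the fit to the E21 and P6 arrays alone. miR-130b from this list was at -1.81 (adjusted p = 0.156, 0.00132 in that fit, range over 14 alternatives 0.000224 to 0.515). At P30 miR-130b was undetected on 1 of 2 arrays, set to 1 signal unit, which widened its spread in the fit to all stages (P30 SD 2.40). Among the largest rises were 2 miRNAs of the miR-129 family, which is enriched in brain. miR-129-2* rose 9.39-fold, from 5.68 ± 0.12 (SD, n = 3) to 8.91 ± 0.15 (SD, n = 3), and miR-129 rose 6.14-fold. miR-29a rose 6.49-fold. The other members of its family were called in neither direction, miR-29c at 7.28 ± 0.10 (SD, n = 3) at E21 and 7.40 ± 0.09 (SD, n = 3) at P6, so that 1 of 3 was higher (1 adjusted over the list alone, median 2.48 as fitted and 1.62 at the bound, camera adjusted p = 0.0642). That list's adjusted p was 0.0451 without P30 replicate 1 (0.503 with an estimated correlation). The others were miR-206 (at least 12.5-fold, undetected at E21), miR-497 (at least 11.8-fold), miR-195 (at least 6.83-fold), miR-126* (at least 6.88-fold, and at least 11.2-fold without E21 replicate 2) and miR-193 (at least 6.10-fold, undetected at E21).

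Of 14 tested neuron-enriched miRNAs, miR-129, miR-132 and miR-128 were higher at P6 and 0 were lower (3 and 0 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.216). miR-132, an activity-regulated miRNA, rose 2.90-fold, whereas miR-212 from the same locus was at -0.28 on the log2 scale (adjusted p = 0.64), so 1 of 2 in that pair was called. The neuronal miR-124 stood at 12.32 ± 0.20 (SD, n = 3) and 12.40 ± 0.31 (SD, n = 3). In the let-7 family, which rises as neurons mature, let-7b (by 1.63 on the log2 scale), let-7c (2.27-fold) and let-7d (1.47-fold) were higher (3 of 8, 3 adjusted over the list alone, median 0.30, camera adjusted p = 0.0642). The list passed without E21 replicate 3 (0.0475) and without P30 replicate 1 (0.0421), where the adjusted p was 0.674 and 0.699 with an estimated correlation. In the miR-15/16 family, miR-497, miR-195 and miR-322 were higher and miR-15b was lower, with the same counts adjusted over the list alone (camera adjusted p = 0.311). Only single members were lower in the miR-181 family (miR-181d) and among 36 tested miRNAs of the imprinted Dlk1-Dio3 cluster (miR-431, 1.85-fold), and 2 of 5 were lower in the group of miR-125, miR-99 and miR-100 members (miR-99b and miR-125a-5p). No member was called in the miR-30 family or the miR-34 family over all miRNAs, where miR-34a alone passed when adjusted over the list alone. The camera adjusted p of these 5 lists was 0.615, 0.478, 0.614, 0.499 and 0.650 in that order. The miR-34 list had a median of -0.18 but a mean of 1.07.

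In all, 67 of 254 tested miRNAs differed between P6 and E21 at an adjusted p under 0.05 in the limma fit, 27 higher and 40 lower at P6, and 89 had an unadjusted p under 0.05. The arrays of the 2 stages did not overlap for 109 of 254 miRNAs, where chance gives 10% for an unfiltered miRNA. The detection filter keeps miRNAs present throughout 1 stage and absent from another, so 10% is not the rate for this set. Without the low-signal arrays (replicate 1 of both stages) the count was 148, and with them as a batch block it was 129. It was 44 without E21 replicate 2 and 43 without P6 replicate 2. The difference of miR-19a was -1.51 within replicate 1 and -1.68 within replicates 2 and 3. The split of 27 higher and 40 lower became 26 and 21 on the values as the authors scaled them, 77 and 71 without the low-signal arrays, and 7 and 0 without any scaling between arrays, where miR-19a was at -1.38 (adjusted p = 0.514, range over 14 alternatives 2.45e-05 to 0.514).

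The second comparison set P30 against E21, the ends of the age range. At P30, miR-19a was undetected on both arrays, at least 68.8-fold lower than the E21 level of 8.76 ± 0.30 (SD, n = 3). The adjusted p of 4.69e-07 belongs to the limma fit and not to this fold. That fit set both P30 arrays to 1 signal unit, which gave them no spread, as for every miRNA undetected on both. miR-17-5p (at least 101-fold, 0 of 2 P30 arrays), miR-18a (at least 47.8-fold, 0 of 2) and miR-20a (at least 209-fold, 1 of 2) were lower as well. miR-19b and miR-92a were still detected on both P30 arrays, 31.3-fold and 17.9-fold below E21. In the other direction, miR-29a, a miRNA that rises in postnatal brain, increased 191-fold, from 4.22 ± 0.07 (SD, n = 3) to 11.80 ± 0.02 (SD, n = 2), with adjusted p = 2.77e-07. miR-129-2* rose 70.2-fold and miR-129-1* 58.4-fold.

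All 6 miR-17~92 members were lower at P30 than at E21 (6 adjusted over the list alone), with a median log2 difference of -5.84 at the bound and -8.50 as fitted (camera adjusted p = 0.000929, and adjusted p = 0.198 with an estimated correlation), and the choice of miR-19a by the study again makes this no independent evidence. All 5 paralog members were lower (5 adjusted over the list alone), among them miR-20b-5p by at least 95.8-fold and miR-93 by 12.1-fold. Their median was -3.60 at the bound and -4.00 as fitted (camera adjusted p = 0.00942, and adjusted p = 0.198 with an estimated correlation). Of the miRNAs reported to target Pten, 11 of 15 were lower and 3 were higher (11 and 3 adjusted over the list alone), with a median of -4.00 (camera adjusted p = 0.00574, and adjusted p = 0.198 with an estimated correlation). The 3 higher members were miR-26a, miR-26b and miR-29b, and miR-21 and miR-301a were among the lower ones. The lower miR-17-5p, miR-19a, miR-19b, miR-20a, miR-93, miR-106b, miR-130b and miR-301a also belong to the cluster, paralog or progenitor-associated lists. This result is therefore not independent of those lists or of the study's choice of miR-19a. All 5 progenitor-associated miRNAs were lower (5 adjusted over the list alone), among them miR-130b (at least 68.7-fold, detected on 1 of 2 P30 arrays) and miR-130a (8.15-fold), with a median of -3.03 (camera adjusted p = 0.0259, and adjusted p = 0.579 with an estimated correlation). miR-216a (at least 33.0-fold) and miR-551b (at least 38.5-fold) complete the 8 largest falls. The fold of miR-551b was at least 58.6 without E21 replicate 1, 19.6 without P30 replicate 1 and at least 68.1 without P30 replicate 2.

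**Figure D3:**
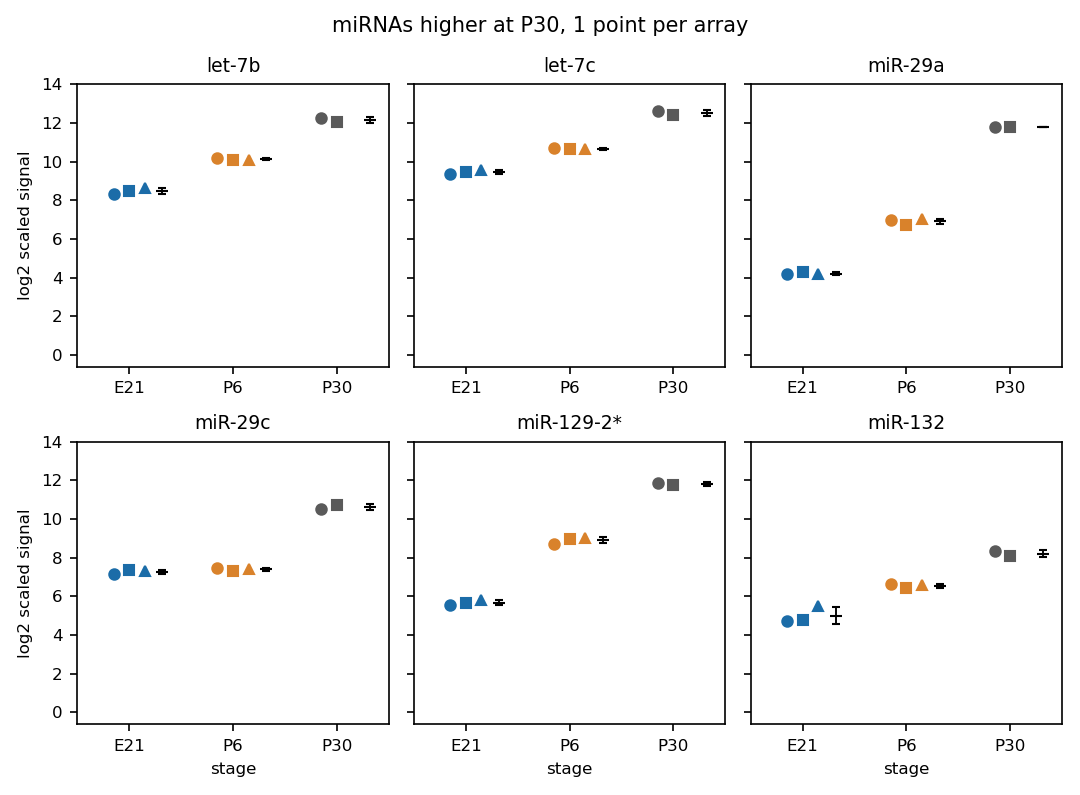
Log2 scaled signal (vertical axis) of let-7b, let-7c, miR-29a, miR-29c, miR-129-2* and miR-132 at E21, P6 and P30 (horizontal axis), with 1 point per array, circles, squares and triangles for replicates 1, 2 and 3, and a bar for the mean ± SD of each stage. miR-29a went from 4.22 at E21 over 6.92 at P6 to 11.80 at P30, whereas miR-29c was at 7.28 and 7.40 before it reached 10.63.

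Of 8 tested let-7 family members, 7 were higher at P30 (7 adjusted over the list alone), let-7b by 12.6-fold, let-7c by 8.24-fold, let-7d by 6.51-fold and let-7a by 3.72-fold, with a median of 1.96 (camera adjusted p = 0.00426, and adjusted p = 0.579 with an estimated correlation). The member not called was let-7i. let-7 probes can share signal between near-identical members. All 3 miR-29 members were higher (3 adjusted over the list alone), with miR-29b at least 61.7-fold and miR-29c 10.2-fold higher (median 5.95 at the bound and 6.81 as fitted, camera adjusted p = 0.0135, and adjusted p = 0.364 with an estimated correlation). Without E21 replicate 1, where it was undetected, the rise of miR-29b was 34.6-fold. The remaining large rises were miR-211 (53.5-fold), miR-34a (at least 50.3-fold), miR-206 (at least 35.7-fold) and miR-129 (27.2-fold). The fold of miR-211 was 81.3 without E21 replicate 1, 102 without P30 replicate 1 and 31.2 without P30 replicate 2. The neuron-enriched list split, with 5 higher and 4 lower of 14 (5 and 4 adjusted over the list alone, median 0.21, camera adjusted p = 0.555). miR-129, miR-132 (9.18-fold), miR-128 (5.56-fold), miR-7a (5.28-fold) and miR-7b were higher. miR-9 (2.51-fold), miR-9*, miR-135b and miR-153 were lower. miR-124 was at 12.57 ± 0.11 (SD, n = 2). Of miR-132 and miR-212 only miR-132 was called.

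Several other families split at P30. In the miR-34 family miR-34a was higher, while miR-34b and miR-34c were undetected at P30 and at least 6.47-fold (at least 11.2-fold without E21 replicate 1) and 6.17-fold lower. That family's median was -2.62 at the bound and -5.28 as fitted (camera adjusted p = 0.712). miR-30b-5p and miR-30c were higher and miR-30a (3.84-fold) and miR-30e were lower (median -0.42, camera adjusted p = 0.951). miR-15b (5.94-fold), miR-16 and miR-322 were lower and miR-195 and miR-497 were higher (median -1.74, camera adjusted p = 0.684). In the miR-181 family miR-181c and miR-181d were lower and miR-181a was higher by 0.66, a direction that turned to -0.17 after quantile normalization (median -0.30, camera adjusted p = 0.779). miR-99b was lower and miR-125b-5p higher by 0.70, which turned to -0.03 after quantile normalization (median 0.52, camera adjusted p = 0.558). Of the 36 Dlk1-Dio3 miRNAs, 12 were higher, among them miR-127 (5.75-fold), and 12 were lower, among them miR-370 (at least 12.2-fold, undetected at P30), miR-431 (6.30-fold) and miR-341 (camera adjusted p = 0.779, median 0.27 but mean -0.22). Counts adjusted over each of these 6 lists alone were the same.

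**Figure D4:**
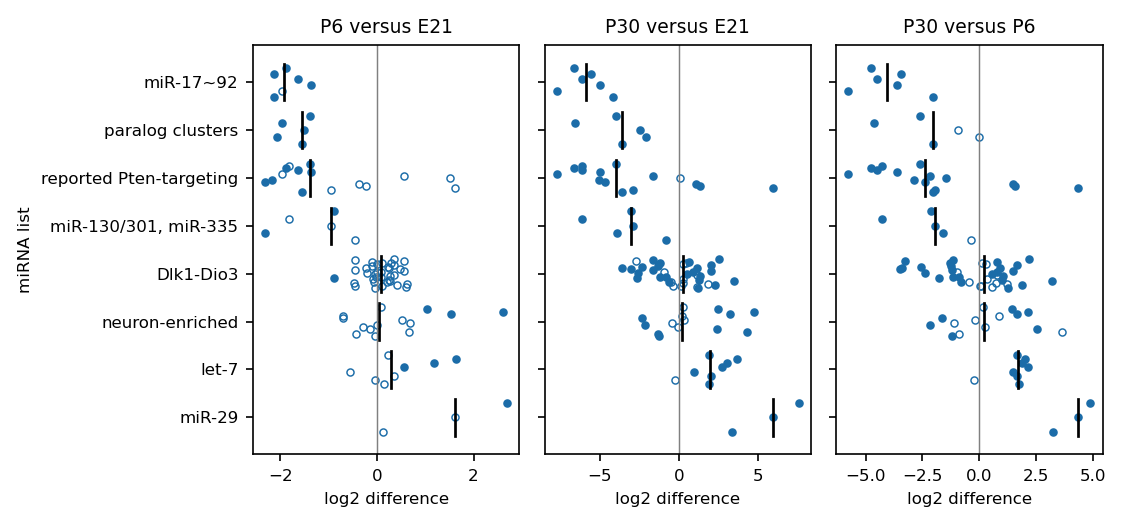
Log2 difference (horizontal axis) of each tested member of 8 miRNA lists (vertical axis) in the 3 comparisons, with undetected values at the lowest detected signal of the array. Filled points passed an adjusted p under 0.05, open points did not, and the black line is the list's median, -5.84 for miR-17~92 and 5.95 for miR-29 at P30 versus E21, while the Dlk1-Dio3 members lay on both sides of 0.

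In all, 148 of 254 miRNAs differed between P30 and E21 in the limma fit, 64 higher and 84 lower at P30, and 32 of the 84 were undetected on both P30 arrays. An unadjusted p under 0.05 was reached by 154 miRNAs. The arrays did not overlap for 189 of 254, where chance gives 20% for an unfiltered miRNA, and the detection filter makes that rate not hold here. Without any scaling between arrays the counts were 23 higher and 51 lower. Lower calls were no longer the majority with only the miRNAs detected on all arrays (98 called, 52 higher and 46 lower) or with median centring (74 higher and 71 lower).

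The third comparison, P30 against P6, covers the postnatal step. miR-19a was at least 22.4-fold lower at P30 than its P6 level of 7.14 ± 0.19 (SD, n = 3). The adjusted p of 1.40e-06 belongs to the limma fit, with both P30 arrays set to 1 signal unit, and not to this fold. All 6 miR-17~92 members were lower (6 adjusted over the list alone), with miR-20a lower by at least 53.8-fold, miR-17-5p by at least 27.3-fold, miR-18a by at least 10.9-fold, miR-19b by 12.1-fold and miR-92a by 4.09-fold. The list had a median of -4.04 at the bound and -6.62 as fitted. Camera, run on the fitted values, gave adjusted p = 0.00196, and adjusted p = 0.290 with an estimated correlation. Here too the study's choice of miR-19a leaves no independent evidence. Of the paralogs, miR-20b-5p (at least 24.6-fold), miR-106b and miR-93 were lower, 3 of 5 over all miRNAs and over the list alone (median -2.04, camera adjusted p = 0.0442, which no longer passed without E21 replicate 1, at 0.0518, without E21 replicate 3, at 0.0579, or without P30 replicate 2, at 0.0637). The call was also lost in the fit to the arrays of the 2 stages (0.0651), without scaling between arrays (0.0523) and with only the miRNAs detected on all arrays (0.106), and the adjusted p was 0.290 with an estimated correlation. Of the miRNAs reported to target Pten, 12 were lower and 3 higher (12 and 3 adjusted over the list alone). Their median was -2.37 at the bound and -3.60 as fitted (camera adjusted p = 0.00705, and adjusted p = 0.290 with an estimated correlation). The overlap with the cluster, paralog and progenitor-associated lists, miR-19a included, holds here too. The other large falls were miR-322 (at least 20.1-fold, undetected at P30), miR-130b (at least 19.6-fold), miR-126 (18.8-fold) and miR-551b (at least 17.6-fold). The fold of miR-551b was 9.48 without P30 replicate 1 and at least 31.1 without P30 replicate 2.

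From P6 to P30, 7 of 8 let-7 family members rose (7 adjusted over the list alone), let-7d by 4.43-fold and let-7b by 4.06-fold (median 1.70, camera adjusted p = 0.00551, and adjusted p = 0.601 with an estimated correlation), and the call was lost after quantile normalization (0.112). All 3 miR-29 members rose (3 adjusted over the list alone), miR-29a by 29.3-fold, miR-29b by 4.32 on the log2 scale and miR-29c by 9.35-fold (median 4.32, camera adjusted p = 0.0272, and adjusted p = 0.422 with an estimated correlation). The other large rises were miR-211 (22.2-fold), miR-31 (at least 11.8-fold), miR-330*, miR-29c* (at least 9.77-fold) and miR-129-1* (9.70-fold). The fold of miR-211 was 39.9 without P30 replicate 1, 39.5 without P6 replicate 1, 13.3 without P6 replicate 3 and 13.0 without P30 replicate 2, where it was not called (adjusted p = 0.0945). Of the neuron-enriched list, 4 were higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.625), with miR-129, miR-132, miR-128 and miR-7a higher, and miR-132 was again called while miR-212 was not. The progenitor-associated list had 4 of 5 members lower (4 adjusted over the list alone, camera adjusted p = 0.0719). It passed without P6 replicate 1 (0.0432), P30 replicate 1 (0.0389) or P30 replicate 2 (0.0442), where the adjusted p was 0.538, 0.601 and 0.576 with an estimated correlation. In the miR-15/16 family 3 were lower, in the miR-34 family 2 were lower, in the miR-181 family 2 were lower, and in the miR-30 family 2 were higher and 2 lower (camera adjusted p = 0.192, 0.533, 0.825 and 0.882). In the group of miR-125, miR-99 and miR-100 members, miR-125a-5p and miR-125b-5p were higher, the latter turning to -0.03 after quantile normalization (camera adjusted p = 0.307). Of the Dlk1-Dio3 miRNAs 12 were higher and 13 lower, 13 and 13 adjusted over the list alone (camera adjusted p = 0.825, median 0.21 but mean -0.31). In total 145 of 254 miRNAs differed between P30 and P6, 62 higher and 83 lower, of which 38 were undetected on both P30 arrays. In all, 159 had an unadjusted p under 0.05. The arrays did not overlap for 190 of 254 miRNAs, where chance gives 20% for an unfiltered miRNA, a rate that the detection filter makes not hold here. Without any scaling between arrays the counts were 9 higher and 53 lower. Higher calls were the majority with only the miRNAs detected on all arrays (59 higher and 41 lower), with the percentile over all miRNAs (73 and 72) and with a floor of 10 (71 and 67).

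Over the 3 stages together, the moderated F test called 165 of 254 miRNAs. Of the tested miRNAs, 21 were lower at both steps, among them miR-19a, miR-17-5p, miR-18a, miR-19b, miR-92a, miR-216a, miR-217 and miR-301b, against 13.1 from independent lists of these sizes. At both steps 12 were higher, against 6.59, namely let-7b, let-7c, let-7d, miR-23b, miR-29a, miR-128, miR-129, miR-129-1*, miR-129-2*, miR-132, miR-206 and miR-383. Both steps use the same P6 arrays, so the lists are not independent, and these overlaps were not tested. Among the 21, miR-374 was undetected at P30, with a P6 mean of 2.61 against a P30 bound of 2.65. Its second fall rests on the value of 1 set for undetected arrays.

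Markers of other cell types that the isolation could carry also moved between stages and single arrays. The cluster of miR-183, miR-96 and miR-182, abundant in photoreceptors, was 4.73 log2 units higher (median of the 3) in P6 replicate 1 than in P6 replicates 2 and 3, with miR-96 at 10.88 against 6.29 and 6.02, and its stage differences were not called (0 of 3 in each comparison, camera adjusted p = 0.823, 0.712 and 0.580). Without P6 replicate 1 camera called the list lower at P6 than at E21 (adjusted p = 0.0443) and higher at P30 than at P6 (adjusted p = 0.0376), at adjusted p = 0.467 and 0.538 with an estimated correlation. miR-211, abundant in pigment epithelium and Mueller glia, rose from 3.36 ± 1.17 (SD, n = 3) at E21 to 9.10 ± 1.10 (SD, n = 2) at P30. miR-204 from the same list was lower by 0.43 at P6 and higher by 0.68 at P30 than at E21, the latter turning to -0.07 after quantile normalization. Both muscle-enriched miRNAs tested, miR-206 and miR-133b, were higher at P6 and at P30 than at E21, and from P6 to P30 miR-206 rose 2.86-fold and miR-133b fell by 0.45, while miR-1 and miR-133a were undetected on every array.

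Vascular and mesenchymal markers were highest at P6. miR-126, an endothelial miRNA, was at 8.17 ± 1.70 (SD, n = 3) at E21, 10.48 ± 0.28 (SD, n = 3) at P6 and 6.25 ± 0.03 (SD, n = 2) at P30, and miR-126* was called higher at P6 than at E21 (1 of 2, 2 adjusted over the list alone) and both were lower at P30 than at P6. The pericyte miRNA miR-145 was detected on the P6 arrays alone and called in both comparisons with P6, whereas miR-143 was called at P6 versus E21 only when adjusted over the list alone. Of the mesenchymal list, 1 of 3 was higher at P6 than at E21 (1 adjusted over the list alone, median 1.57 at the bound and 2.71 as fitted, camera adjusted p = 0.0312), and 3 were lower at P30 than at P6 (camera adjusted p = 0.133). For the first, the adjusted p with an estimated correlation was 0.347, and it passed in 10 of 16 alternatives and in 5 of 8 fits that left out an array, at 0.0537 without E21 replicate 2, 0.0524 without E21 replicate 3 and 0.0816 without P6 replicate 1. Neither the endothelial, the pericyte nor the mesenchymal list had a called member at P30 versus E21 (camera adjusted p = 0.805 for the last, median 0.05 at the bound and -1.41 as fitted).

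**Figure D5:**
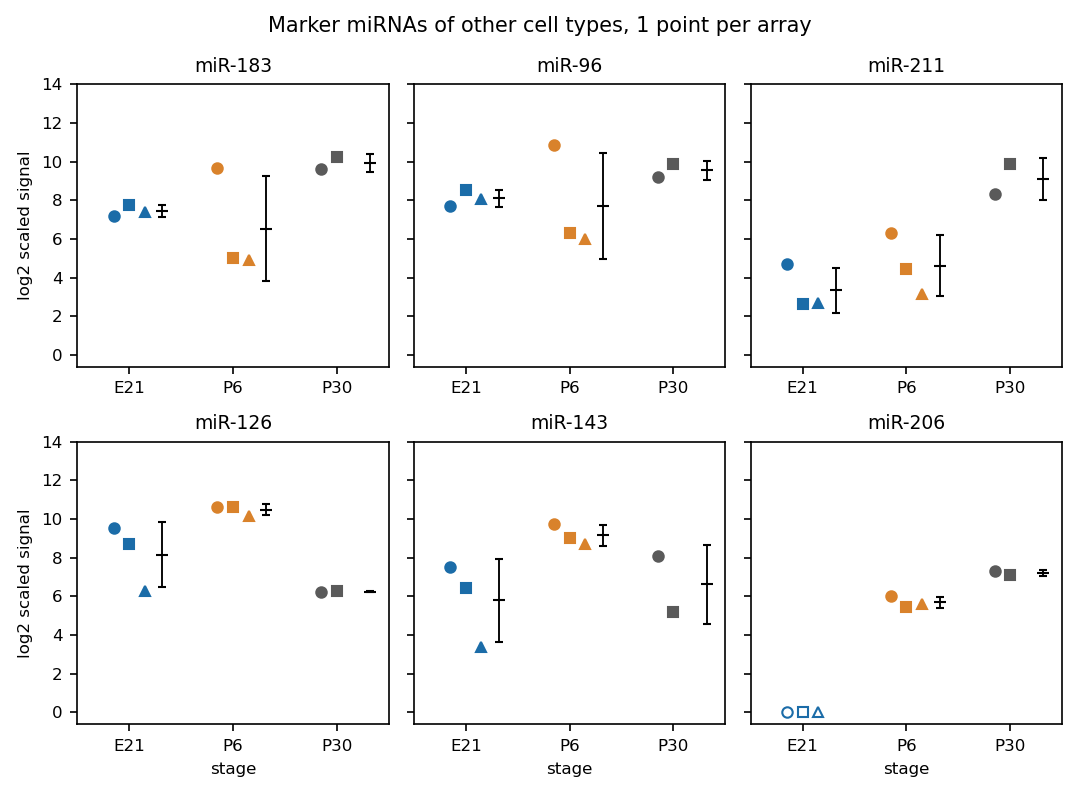
Log2 scaled signal (vertical axis) of marker miRNAs of photoreceptors (miR-183, miR-96), pigment epithelium and Mueller glia (miR-211), endothelium (miR-126), pericytes (miR-143) and muscle (miR-206) at E21, P6 and P30 (horizontal axis), with 1 point per array, circles, squares and triangles for replicates 1, 2 and 3, open points at 0 where undetected, and a bar for the mean ± SD of stages in which all arrays detected the miRNA. P6 replicate 1 stood at 9.66 for miR-183 while replicates 2 and 3 stood at 5.04 and 4.92.

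Of 7 miRNAs higher in glia than in neurons, miR-23a, miR-23b, miR-24 and miR-27a were higher at P6 than at E21 (4, and 6 adjusted over the list alone, median 0.57, camera adjusted p = 0.0123, and adjusted p = 0.347 with an estimated correlation). At P30, miR-22, miR-23a, miR-23b and miR-24 were higher and miR-21 lower than at E21 (camera adjusted p = 0.359), and 2 were higher and 2 lower than at P6 (3 and 3 adjusted over the list alone, camera adjusted p = 0.825, median 0.64 but mean -0.14). The oligodendrocyte miRNA miR-219-5p was undetected at P30, at least 9.72-fold below E21 (at least 19.0-fold without E21 replicate 1) and at least 5.39-fold below P6, and miR-338 was not called in any comparison. Of 4 tested miRNAs of microglia and leukocytes, miR-342-3p was lower at P6 than at E21 by 0.89 (1 lower, with 1 higher and 1 lower adjusted over the list alone) and was called higher at P30 than at P6 together with a lower miR-146a (camera adjusted p = 0.788, 0.990 and 0.882 for P6 versus E21, P30 versus E21 and P30 versus P6). Of the stem cell clusters miR-290 alone was tested and was not called. No erythroid or epithelial marker met the detection rule, and 1 miRNA of each of those lists was detected on at least 1 array. The erythroid miR-451 (12.8 and 28.8 signal units) and the leukocyte miR-142-3p (17.6 and 8.05) were detected on P6 replicates 2 and 3 alone.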

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

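The tests of photoreceptor carry-over, fewer dividing cells, vascular carry-over and higher P6 sensitivity were chosen after the result was seen, and so were the alternatives on the low-signal arrays. Features outside the comparisons carried signal. Of 22 control features, 7 were above the shared lowest value on at least 1 array, among them hur_6 with 20848 and 24940 signal units on replicate 1 of E21 and P6 against 52644 to 67415 on the other E21 and P6 arrays. Of the miRNAs left out of the tests, 54 were detected on at least 1 array, 37 of them on at most 2 arrays. Of these 54, 4 were detected on both low-signal arrays and on none of the other E21 and P6 arrays.

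Replicate 1 of E21 and replicate 1 of P6 departed from replicates 2 and 3 in a shared way, with deviations from the stage mean that correlated at 0.634 across miRNAs, which are not independent replicates. Loss of dim miRNAs on these low-signal arrays is argued against by a correlation of 0.494 over the 81 brighter miRNAs detected on all arrays, and a distortion that quantile normalization removes by one of 0.662 after it. Photoreceptor and bipolar cells in both arrays are argued against by the median of miR-183, miR-96 and miR-182, which was 4.73 above replicates 2 and 3 in P6 replicate 1 but -0.39 in E21 replicate 1. Control features differed as well. hur_2, hur_4, hur_6 and miRNABrightCorner30 were lower on both arrays than on the other E21 and P6 arrays, miRNABrightCorner30 at 248 and 292 against 405 to 549. hur_1 was higher on both (72959 and 83814 against 55703 to 68914), and hur_5 and mr_1 did not part them. A shared batch that the labels do not record may have set both arrays apart and stays open, as does a biological difference between litters or preparations, which was not tested. Of the 67 miRNAs called between P6 and E21, 61 were also among the 148 called without both arrays.

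The miR-17~92 members miR-17-5p, miR-18a and miR-19a were undetected on both P30 arrays. A lower sensitivity of the P30 arrays is argued against by the other tested miRNAs at least as bright at E21, of which a share of 0.0175 (1 of 57, the paralog miR-20b-5p) was undetected on both. Scaling is argued against by the median difference of the cluster, which lay between -6.31 and -5.10 under 6 scalings, that of the report included. Fewer dividing or progenitor cells in the isolate at later stages may contribute and stay open, since the progenitor-associated list had a median of -3.03 and no marker separates them from a fall within ganglion cells. The age of the animals, a biological difference the design names, is likewise open.

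The 7 tested endothelial, pericyte and mesenchymal miRNAs had their highest stage mean at P6 in 7 of 7 cases. Vascular and mesenchymal cells carried over at P6 could give this pattern, with miR-126 at 10.48 and miR-143 at 9.15 at P6, and the labels do not say whether the isolation kit removes such cells. A higher sensitivity of the P6 arrays is argued against by the differences with undetected values at the lowest detected signal, where all 7 stayed higher at P6, by a median of 1.79 over E21 (1.51 to 3.36) and 2.52 over P30 (0.97 to 4.23), although miR-145 was 1.58-fold over E21 and 1.01-fold over P30 without P6 replicate 1 (4.97-fold and 3.28-fold without P6 replicate 3). A change of these miRNAs with age within ganglion cells was not tested. Among the tested microglia and leukocyte miRNAs, miR-146a and miR-150 also had their highest stage mean at P6, whereas miR-223 and miR-342-3p did not. The 7 endothelial, pericyte and mesenchymal miRNAs are not independent cases. miR-126 and miR-126* are arms of a single precursor, as are miR-199a-3p and miR-199a-5p. The genes of miR-214 and miR-199a are neighbours, as are those of miR-143 and miR-145. miR-214 is also in the list of miRNAs reported to target Pten.

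Of the 10 splits of the 6 E21 and P6 arrays into groups of 3, 1 gave as many called miRNAs as the real split, namely the real split itself with 67, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.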

How the results depend on the processing

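The alternatives on the low-signal arrays were chosen after the results were seen, and the others before. miR-19a kept its direction in every setting run, and its call in each except that without any scaling between arrays, where P6 versus E21 was -1.38 (adjusted p = 0.514). Without scaling the counts were 7 for P6 versus E21, 74 for P30 versus E21, 62 for P30 versus P6 and 70 over all stages. The arrays then differ in total signal, which widens the spread within stages. With only the miRNAs detected on all 8 arrays, the counts were 42 for P6 versus E21, 98 for P30 versus E21, 100 for P30 versus P6 (59 higher and 41 lower) and 109 over all stages, and list calls 4, from fewer miRNAs tested. That setting ended the calls of the paralogs (P6 versus E21, 0.0545, and P30 versus P6, 0.106), of the miRNAs reported to target Pten (0.126, 0.0965 and 0.117 in the 3 comparisons) and of the progenitor-associated list (P30 versus E21, 0.0965). Array weights gave 151 for P6 versus E21, leaving out the low-signal arrays 148 and a batch block for them 129, and the cause was not tested. List calls, 16 as reported, were 25 without a detection filter, where most variances were 0 so that the fit is unreliable, 0 with an estimated correlation and 31 with fry, which asks another question. The replicate block gave 60, 157 and 151, 18 list calls, and adjusted p = 0.00624 for miR-19a, P6 versus E21 (range over its 14 alternatives 2.45e-05 to 0.514). Among 237 results for named miRNAs that block ended 9 calls and gained 5.

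Leaving out each array in turn gave 43 to 87 miRNAs for P6 versus E21, 115 to 159 for P30 versus E21, 113 to 157 for P30 versus P6, 119 to 173 over all stages and 14 to 20 list calls. For P6 versus E21 the count was 43 without P6 replicate 2 and 44 without E21 replicate 2. For miR-19a the range was -1.74 to -1.45 (highest adjusted p = 0.0114), -6.34 to -5.79, and -4.73 to -4.17. Where 1 P30 array is left out, the remaining one is assumed to vary like the other stages.

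Among the 164 called results for named miRNAs, the direction turned in 5 cases, none of them past the threshold after turning, and other called miRNAs were not compared one by one. After quantile normalization miR-181a (-0.17), miR-125b-5p (-0.0329) and miR-204 (-0.0714) turned at P30 versus E21, and miR-125b-5p (-0.0329) at P30 versus P6. Without scaling miR-342-3p turned at P30 versus P6 (-0.00928). The cause was not tested. Of these 164 results, 69 kept their call in every setting, 118 in every setting but no scaling, and 131 in each of the 8 fits that left out an array.

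The share of higher miRNAs moved with the scaling. The median over all tested miRNAs was -0.15, -0.05 and -0.07 for P6 versus E21, P30 versus E21 and P30 versus P6, and became -0.29, 0.01 and 0.19 with the percentile over all miRNAs, -0.02, 0.26 and 0.19 with median centring, 0.09, -0.49 and -0.76 without scaling, and 0.11, 0.14 and -0.17 with the authors' values. Signals near the lowest detected value, 2.74 to 4.78 signal units per array, limit what can be said of dim miRNAs.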

Other observations

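The comparison of precursor arms one by one was chosen after the result was seen, and the tests of neighbouring genes, of the correlation between arms and of the Dlk1-Dio3 spread were not. Opposite arms of a precursor could differ in their course. Among 18 precursors with both arms detected on all arrays, the difference between arms was called for 9 at P30 versus E21, for 8 at P30 versus P6 and for 0 at P6 versus E21. At P30 versus E21, 4 precursors had both arms called in opposite directions, all 4 from the Dlk1-Dio3 list, and at P30 versus P6 7 did, of which miR-30a, miR-30e and miR-324 are outside that list. miR-127 was higher by 2.52 and miR-127* lower at -1.28, a difference of 3.81 (SE 0.270, adjusted p = 2.39e-05 in limma), and the others of these 4 were miR-376b, miR-411 and miR-434. The Dlk1-Dio3 list also held miR-136, miR-154, miR-409 and miR-433 among the 18, whose arms were not called in opposite directions. Whether opposite arms are more frequent in that list was not tested. Over 37 precursors with both arms tested, the correlation between arms at P30 versus E21 was r = 0.30 (permutation p = 0.0666) and rho = 0.21 (permutation p = 0.208), and r = 0.31 without the 2 farthest precursors. These differences had undetected values at the bound, so r, rho and p depend on that setting. An arm near the lowest signal can then show little fall, as miR-20a* at -0.41 beside miR-20a at -7.71. Over the 18 precursors with both arms detected on all arrays the sign turned, with r = -0.34 at P30 versus E21 and r = -0.20 at P30 versus P6 (0.54 at P6 versus E21), which were not tested. These values are across miRNAs, which are not independent replicates, and a p that misses the threshold does not exclude that arms change together.

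Neighbouring miRNA genes may change together. Over 318 pairs of tested miRNAs within 10 kb, from 25 genomic clusters, the median absolute difference in log2 fold change at P30 versus E21 was 1.42 against 1.92 in permuted data (one-sided permutation p = 0.0071, adjusted over the 3 comparisons 0.0071). At P6 versus E21 it was 0.35 against 0.85, with p = 1e-04, the smallest these permutations can give (adjusted 3e-04), and at P30 versus P6 1.28 against 1.72 (p = 0.0044, adjusted 0.0066). Among the 50 pairs outside the Dlk1-Dio3 list p was 3e-04, 0.0024 and 0.0115 for P6 versus E21, P30 versus E21 and P30 versus P6. All these fold changes had undetected values at the bound, so the results depend on that setting. Some neighbours are family members whose probes can share signal, such as miR-106b with miR-93 and miR-181c with miR-181d. Shared signal could make neighbours alike and was not tested. The 3 genomic clusters of the Dlk1-Dio3 list had a mean spread of 1.43 against 1.47 in 22 other clusters (exact one-sided permutation p = 0.476). Over single pairs, which are not independent within a cluster, the median was 1.46 in 268 pairs of the list against 1.07 in the 50 others, and 3 clusters are too few to exclude a larger spread.

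Between the stages, 10 miRNAs were higher at P6 than at E21 and lower at P30 than at P6, against 8.82 from independent lists, among them miR-322, miR-542-3p and miR-542-5p beside the vascular miR-126* and miR-145 and the mesenchymal miR-199a-5p. Of these 10, miR-874 was called only through the value of 1 set for undetected arrays. Its P6 mean was 2.03, against bounds of 2.05 at E21 and 2.65 at P30. In the opposite order 8 were lower and then higher, against 9.76, among them miR-204, miR-342-3p and miR-125a-5p. Both sets share the P6 arrays between the steps, so noise in those arrays alone can add to both. The values of 8.82 and 9.76 are therefore not counts under no change, and these overlaps were not tested.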
